A study of Mus musculus with 16 samples.

How the data were processed

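RNA sequencing was done on sorted medullary thymic epithelial cells of C57BL6 mice that carried Aire-CreERT2 and the Ai14 reporter. Per the labels' protocols, mice of both sexes aged 5 to 6 weeks received 2 mg tamoxifen and were taken 7 days later, and 12 thymi were pooled per biological replicate. The thymi were digested with Liberase and DNase and enriched on Percoll, and live CD45-negative EPCAM-positive cells were sorted by RFP and MHC class II into lysis buffer, a gate that holds no cortical epithelial marker. RNA was selected on poly(A) beads, amplified with the NuGen Ovation V2 kit and made into Nextera XT libraries, per the labels' protocols. The deposited files hold raw counts per Ensembl gene for 43432 genes, made by the authors from STAR alignments to GRCm38, per the submitters' processing notes. Those notes also name DESeq2, without a version. The annotation release, the counting tool and the strand setting are not given in the sources used here, so reads on overlapping or antisense genes may have been counted for either.

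Gene symbols and coordinates were taken from GENCODE M21 for GRCm38, which matched 42462 gene identifiers. The 970 without a symbol held 0.11% of the reads, and 40 identifiers shared a symbol with another. Members of families with similar sequences, such as kallikreins, taste receptors, globins, antibody and T cell receptor segments, Ear, Cyp2b and Saa genes, can share reads, and their single values are uncertain to that extent. Library totals were 7.93 to 19.46 M, with population means of 15.5 M in RFP- MHCIIhi, 15.0 M in RFP+ MHCIIhi, 12.6 M in RFP- MHCIIlo and 9.97 M in RFP+ MHCIIlo. Libraries of a population were checked for being copies or technical repeats of each other: over 24 pairs the chi-square per degree of freedom was 3.2 to 37.16, above the value of 1 that repeats of the same library would give.

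Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 19617, and libraries were scaled by TMM. All 16 libraries entered 1 quasi-likelihood fit with a mean per population. The contrasts were RFP+ MHCIIlo against RFP- MHCIIlo, RFP+ MHCIIlo against RFP+ MHCIIhi, RFP+ MHCIIhi against RFP- MHCIIhi, RFP- MHCIIlo against RFP- MHCIIhi, and the RFP difference in MHCIIlo minus that in MHCIIhi. P-values were adjusted by Benjamini and Hochberg within each contrast, with a threshold of 0.05. CPM are TMM-normalised counts per M, and log2 values used a prior count of 2. Principal components were computed from the 500 most variable genes. A gene was assigned to a population as its own when it exceeded each of the 3 others by more than 1 on the log2 scale with an adjusted p under 0.05.

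On simulated counts drawn from these libraries with 200 changed genes, the fit of RFP+ MHCIIlo against RFP- MHCIIlo recovered 46, 74, 98 and 100% of genes changed 1.5, 2, 4 and 8-fold (18905 genes), with 4 unchanged genes called. The corresponding shares were 30, 80, 100 and 98% for RFP+ MHCIIlo against RFP+ MHCIIhi (18886 genes, 15 unchanged called) and 54, 74, 96 and 100% for RFP+ MHCIIhi against RFP- MHCIIhi (18844 genes, 10 unchanged called). For RFP- MHCIIlo against RFP- MHCIIhi they were 44, 82, 96 and 100% (18916 genes, 11 unchanged called), and for the difference of RFP effects 16, 66, 94 and 100% (18872 genes, 7 unchanged called). The simulated populations shared a common mean apart from the 200 changed genes, which were drawn from the better expressed genes. In the real contrasts 34.1 to 69.1% of genes were called, so these shares need not carry over to them.

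The sentinel genes, the gene lists and the rule for naming further genes from the results were fixed before the data were examined. The named genes are the sentinels of each list and, among called genes with a mean of at least 20 CPM in the higher population and no overlap between libraries (not asked for the difference of RFP effects), those with the largest log2 change. These were 8 per direction for both contrasts of RFP+ MHCIIlo with another population, 5 for the other contrasts of a pair and 4 for the difference of RFP effects. Predicted genes were passed over, and 6 genes of RFP+ MHCIIlo's own were added. Other list members were named as examples after their values were seen. The 26 tested lists cover thymic epithelial states, mTEC resembling other tissues, blood and stromal cell types, stress, interferon, chemokine and mitochondrial genes, and the MHC class II list is the gate marker itself. Lists were tested with camera from limma 3.58.1 at its preset correlation of 0.01, adjusted over 26 lists and 5 contrasts, and again with the correlation estimated from the data and with fry. The fry test asks whether a list moves in 1 direction and does not compare it with other genes. Of the taste receptors 28 of 38 could be tested, and Ccl21a, Mup1, Rbp3, Hba-a2 and Tnnc2 were among the genes left out of the tests for low counts, as were 6 of 13 mitochondrial genes. How reads shared by similar genes were counted is not given, so low counts do not show that these genes were silent.

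Genes detected were counted after thinning to 7929533 reads per library, with at least 5 reads, and compared by two-sided exact permutation with adjustment over 4 comparisons. Alternatives were median-ratio and upper-quartile scaling, no filter and a filter of 5 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, a test for a fold beyond 2, a fit of only the 8 libraries of each pair, the replicate number as a block, and each library left out in turn. Detection was repeated with at least 1 and 20 reads and at 1 CPM. Another 3 alternatives were chosen after seeing the data: without genes that resemble ribosomal RNA, without RFP+ MHCIIlo replicates 1 and 4, and without RFP- MHCIIhi replicates 3 and 4. Replicate numbers were not taken to pair the samples, since residuals of libraries with the same number correlated at -0.019 to 0.129 (median 0.057, 4 of 24 over 0.1). The best match of a library nevertheless had its own number in 35 of 48 comparisons, more than chance would give, and other pairs had a median of -0.017. Shared pools therefore cannot be excluded, and the main fit makes no use of them. Detection and figures used numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.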

Results

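Gene expression was measured by RNA sequencing in 4 populations of mouse medullary thymic epithelial cells (mTEC), the stromal cells of the thymic medulla that display tissue-restricted antigens to developing T cells. The mice carried a tamoxifen-inducible Cre under control of Aire, the transcription factor that drives much of this antigen expression, together with the Ai14 reporter, in which Cre permanently switches on a red fluorescent protein (RFP). After 2 mg tamoxifen and 7 days, RFP marks cells that expressed Aire at the time of the pulse and their descendants. Cells that expressed Aire only before or after the pulse carry no label, so RFP- cells may have an Aire history. Cells negative for the blood cell marker CD45 and positive for the epithelial marker EPCAM were sorted by RFP and by surface MHC class II into RFP- MHCIIhi, RFP+ MHCIIhi, RFP- MHCIIlo and RFP+ MHCIIlo. Each population had 4 libraries, numbered as biological replicates of 12 pooled thymi, so p-values measure the spread between pools. The 16 libraries held 7.93 to 19.46 M counted reads (median 13.28 M, where M is mega). Levels are normalised counts per M (CPM) given as mean ± SD with n = 4 libraries per population, and differences are log2 fold changes from 1 fit over 19617 tested genes.

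The 4 populations separated on the first principal components, which held 86.8% and 6% of the variance of the 500 most variable genes. Component 1 followed the MHC class II gate and component 2 the RFP gate. The RFP+ MHCIIlo libraries came from 19400 to 20500 sorted cells and those of the other populations from at least 80500. Correlations of log2 CPM between libraries of a population were 0.9495 to 0.9674 in RFP+ MHCIIlo and 0.9869 to 0.9905 in RFP- MHCIIhi. RFP+ MHCIIlo replicates 1 and 4 stood apart on components 3 and 4, with scores of -15.3 and 18.8. Mitochondrial ribosomal RNA took 42.7 ± 3.06% of reads in RFP- MHCIIlo and 31.3 ± 1.43% in RFP+ MHCIIhi, and nuclear transcripts that resemble ribosomal RNA took 4.08 ± 1.2% in RFP+ MHCIIlo and 1.83 ± 0.414% in RFP- MHCIIhi (SD, n = 4 each).

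**Figure D1:**
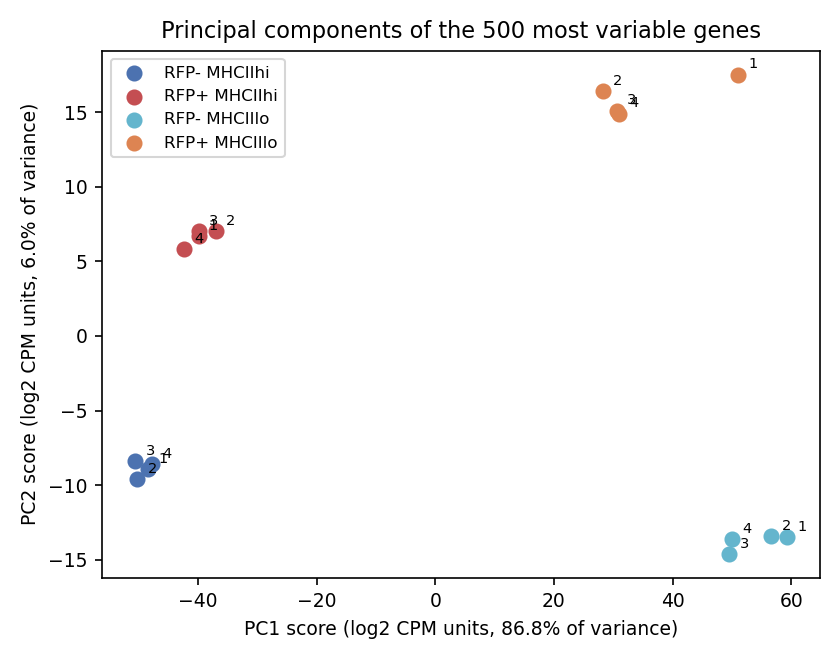
Scores of the 16 libraries on principal components 1 and 2 of the 500 most variable genes (log2 CPM units, with the share of variance on each axis); colours mark the 4 populations and small numbers the replicates. The MHCIIhi populations lie at negative and the MHCIIlo populations at positive scores of component 1, and RFP+ MHCIIlo replicate 1 lies at 51 where the other RFP+ MHCIIlo libraries lie at 28.2 to 30.9.

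Among MHCIIlo cells, keratinocyte genes and the listed intestinal and liver genes were higher with the RFP label. Basal epithelial genes, the parathyroid hormone gene Pth and the matrix genes Prelp and Fmod were lower. This comparison asks how cells with a history of Aire expression differ from unlabelled cells at low MHC class II. Krt1 and Krt10, the keratins of the suprabasal epidermis, reached 261 ± 70.3 and 319 ± 84.2 CPM in RFP+ MHCIIlo against 16.9 ± 4.15 and 26.4 ± 7.59 CPM in RFP- MHCIIlo (SD, n = 4 each). Their log2 differences were 3.96 (SE 0.19, adjusted p = 3.7e-14) and 3.61 (SE 0.19, adjusted p = 2.2e-13). Ttr, the liver's thyroid hormone carrier, was 22.3-fold higher, at 87.2 ± 18.4 against 3.91 ± 0.93 CPM (log2 4.48, SE 0.17, adjusted p = 1.8e-15). Pth fell from 427 ± 197 CPM to 8.42 ± 15.9 CPM (log2 -5.67, SE 0.69, adjusted p = 2.8e-07). Aire itself was at 50.8 ± 25.4 CPM in the labelled and 37.9 ± 23.5 CPM in the unlabelled MHCIIlo cells (log2 0.42, SE 0.34, adjusted p = 0.31).

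The identities of these genes, on GRCm38 with the GENCODE M21 annotation, are as follows, each being a protein-coding gene. Aire (ENSMUSG00000000731) lies on chromosome 10 at 78030022 to 78043610, Krt1 (ENSMUSG00000046834) on chromosome 15 at 101845426 to 101850794 and Krt10 (ENSMUSG00000019761) on chromosome 11 at 99385254 to 99389364. Ttr (ENSMUSG00000061808) lies on chromosome 18 at 20665280 to 20674321 and Pth (ENSMUSG00000059077) on chromosome 7 at 113385580 to 113388570. Dclk1 (ENSMUSG00000027797) lies on chromosome 3 at 55242364 to 55539068, Pou2f3 (ENSMUSG00000032015) on chromosome 9 at 43123939 to 43210369, Mki67 (ENSMUSG00000031004) on chromosome 7 at 135689784 to 135716361 and Rag1 (ENSMUSG00000061311) on chromosome 2 at 101638282 to 101649501.

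Of 32 tested genes of cornified epithelium, 31 rose and 0 fell in RFP+ MHCIIlo against RFP- MHCIIlo, with the same counts adjusted over the list alone. Their median log2 difference was 3.01 (camera adjusted p = 7.1e-51; adjusted p = 0.0059 with an estimated correlation). Besides Krt1 and Krt10 these included the cornified envelope genes Ivl (3.22, SE 0.17) and Lor (3.68, SE 0.33, and 4.44 without RFP- MHCIIlo replicate 1). Krt77 rose from 17.0 ± 8.22 to 259.9 ± 76.2 CPM. Cyp2b19, a cytochrome of keratinocytes, rose by 3.86 (SE 0.22) and the kallikrein protease gene Klk13 by 3.85 (SE 0.14). All 12 genes of the enterocyte and hepatocyte list rose, also adjusted over the list alone (median 2.35, adjusted p = 4.1e-25; adjusted p = 0.0025 with an estimated correlation). Among them were the acute-phase gene Saa3 (4.09, SE 0.11) and the antimicrobial lectin gene Reg3g, at 2982 ± 533 against 830.0 ± 77.5 CPM. Ear1, a ribonuclease gene with close paralogs, rose from 1.61 ± 0.59 to 22.0 ± 4.10 CPM.

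Of 14 ciliated cell genes, 13 rose and 0 fell, also adjusted over the list alone (median 1.57, adjusted p = 5.5e-09; adjusted p = 0.042 with an estimated correlation). Foxj1, the master regulator of motile cilia, rose from 33.0 ± 4.11 to 108 ± 5.59 CPM (1.71, SE 0.10). Tuft cells are chemosensory epithelial cells, and of their 32 genes 29 rose and 1 fell, also adjusted over the list alone (median 0.95, adjusted p = 1.5e-08; adjusted p = 0.26 with an estimated correlation). Their regulator Pou2f3 rose by 1.36 (SE 0.12), the kinase gene Dclk1 by 0.74 (SE 0.15), the taste channel gene Trpm5 by 0.92 (SE 0.13) and the cytokine gene Il25 by 0.88 (SE 0.22). Of 9 genes of microfold cells, which carry luminal antigen across the gut wall, 8 rose and 1 fell, with the same counts adjusted over the list alone (median 0.59, adjusted p = 0.0068; adjusted p = 0.14 with an estimated correlation). The microfold receptor gene Gp2 rose by 0.71 (SE 0.09) and the chemokine gene Ccl20 by 0.85 (SE 0.14).

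Of 9 tested genes chosen as antigens known to depend on Aire, 7 rose and 0 fell, also adjusted over the list alone (median 3.12, adjusted p = 6.5e-05; adjusted p = 0.14 with an estimated correlation). Tff3, a secreted goblet cell peptide gene, rose from 4.15 ± 2.08 to 66.7 ± 20.6 CPM and Mucl2, the salivary gene once named Spt1, from 0.38 ± 0.21 to 10.4 ± 1.66 CPM. The insulin gene Ins2 was at 0.20 ± 0.23 CPM in RFP- MHCIIlo and 1.88 ± 0.46 CPM in RFP+ MHCIIlo (adjusted p = 3.7e-06). The urinary protein gene Mup1, with 14 reads over all libraries, was not tested. Of the antigens known not to need Aire, Gad1, the GABA-synthesising enzyme, rose by 1.06 (SE 0.26), and the liver gene Crp fell by 2.19 (SE 0.15), from 34.4 ± 4.48 to 7.46 ± 1.10 CPM. Only these 2 genes were listed, so that list was not tested as a group.

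Of 11 genes of immature or CCL21-type mTEC, 2 rose and 7 fell (8 fell adjusted over the list alone; median -1.49, adjusted p = 1.6e-06; adjusted p = 0.0093 with an estimated correlation). The basal keratin gene Krt5 fell from 1342 ± 190.2 to 470.3 ± 9.13 CPM and the basal cell regulator Trp63 by 1.71 (SE 0.08). Pdpn, the surface glycoprotein podoplanin, fell by 2.94 (SE 0.13). Dapl1, on the list and known in differentiating epithelium, rose by 2.77 (SE 0.10). Ccl21a, the namesake chemokine, had 1 read over all libraries and could not be tested, and this low count does not show its absence. Of 30 cell cycle genes 26 fell and 0 rose (27 fell adjusted over the list alone; median -1.15, adjusted p = 2.3e-07; adjusted p = 0.35 with an estimated correlation). Mki67, the proliferation marker, fell by 2.06 (SE 0.26), and Top2a, the topoisomerase of dividing cells, by 1.23 (SE 0.22). Interferon response genes fell in 10 of 11 cases, also adjusted over the list alone (median -0.82, adjusted p = 1.3e-06; adjusted p = 0.069 with an estimated correlation), with Isg15 down from 71.9 ± 10.9 to 33.9 ± 3.85 CPM.

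The matrix proteoglycan genes Prelp and Fmod, among the largest decreases, fell from 137 ± 24.7 and 64 ± 9.88 CPM to 4.35 ± 1.39 and 2.31 ± 0.71 CPM. Cav1, a membrane scaffold of stromal and endothelial cells, fell by 4.88 (SE 0.28) and the growth factor binding protein gene Igfbp6 by 3.97 (SE 0.41). Upk3b, a mesothelial marker, fell from 62.8 ± 42.5 to 1.95 ± 2.41 CPM and the sodium channel gene Scn1a from 30.4 ± 9.37 to 0.68 ± 0.84 CPM. Markers of stromal cell types moved with them. Of 10 mesenchymal genes 8 fell and 0 rose, also adjusted over the list alone (median -1.78, adjusted p = 1.5e-05; adjusted p = 0.22 with an estimated correlation), with Col1a1, a fibroblast collagen, down by 1.85 (SE 0.33) and Dcn by 3.52 (SE 0.22). Of 9 endothelial genes 6 fell and 2 rose, also adjusted over the list alone (median -1.78, adjusted p = 0.047; adjusted p = 0.24 with an estimated correlation), with Pecam1, an endothelial junction gene, down by 1.78 (SE 0.20). The endothelial list no longer passed without RFP- MHCIIlo replicate 1 (adjusted p = 0.0696) or RFP+ MHCIIlo replicate 1, 2 or 4 (adjusted p = 0.0667, 0.0572 and 0.0515). With the replicate number as a block it did not pass either (camera adjusted p = 0.0662). The B cell, thymocyte and myeloid lists had more genes up than down and the erythroid list the reverse, all without a call. Of 8 B cell genes 5 rose and 0 fell, also adjusted over the list alone (median 1.22, adjusted p = 0.076), though Cd79a stood at 0.58 ± 0.30 against 0.74 ± 0.32 CPM (adjusted p = 0.57). Of 16 thymocyte genes 7 rose and 1 fell, also adjusted over the list alone (median 0.83, adjusted p = 0.38). Cd3e rose by 1.16 (SE 0.42) and Cd8a by 1.11 (SE 0.39), while Rag1 did not pass (adjusted p = 0.17; 0.00071 to 0.54 over the alternatives, with 0.043 without RFP+ MHCIIlo replicate 1 and 0.00071 with no filter). The call of Cd3e was lost without RFP- MHCIIlo replicate 1 (adjusted p = 0.072) or RFP+ MHCIIlo replicate 3 (0.13) and with limma-voom (0.19; 8.8e-07 to 0.19 over the alternatives). That of Cd8a was lost without RFP- MHCIIlo replicate 4 (0.069) or RFP+ MHCIIlo replicate 3 or 4 (0.091 and 0.085) and with limma-voom (0.17; 6.4e-07 to 0.17 over the alternatives). Of 16 myeloid genes 7 rose and 0 fell (5 and 0 adjusted over the list alone; median 0.68, adjusted p = 0.19, and 0.0344 without RFP+ MHCIIlo replicate 1), with Lyz2 at 137 ± 22.6 against 78.1 ± 16.7 CPM. C1qa, at 0.98 ± 1.24 against 1.18 ± 0.51 CPM, did not pass (adjusted p = 0.69; 0.007 to 0.97 over the alternatives), though it fell by 1.78 without RFP+ MHCIIlo replicate 3 (adjusted p = 0.007), and its sign turned without RFP+ MHCIIlo replicate 1 (0.03) or 4 (0.13). Of 4 erythroid genes 3 fell and 0 rose, also adjusted over the list alone (median -2.43, adjusted p = 0.25). Hbb-bs fell by 1.77 (SE 0.56, adjusted p = 0.011; 0.00064 to 0.089 over the alternatives), from 1.95 ± 1.52 to 0.53 ± 0.44 CPM, and gave -1.14 without RFP- MHCIIlo replicate 1, where it was not called (adjusted p = 0.089), and -3.41 without RFP+ MHCIIlo replicates 1 and 4. Of 7 mitochondrially encoded genes, a measure of RNA quality, 6 fell, also adjusted over the list alone (median -0.39, adjusted p = 0.031; adjusted p = 0.41 with an estimated correlation).

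The MHC class II list is the gate marker itself. Within the MHCIIlo gate 8 of its 10 genes fell and 1 rose with the RFP label, also adjusted over the list alone (median -0.53, adjusted p = 0.0087; adjusted p = 0.42 with an estimated correlation). H2-Aa fell by 0.46 (SE 0.13), and Cd74, the invariant chain, by 0.38 (SE 0.15, adjusted p = 0.043). The Cd74 call ended without RFP- MHCIIlo replicate 3 or 4 (adjusted p = 0.11 and 0.13) or RFP+ MHCIIlo replicate 1 or 2 (adjusted p = 0.15 and 0.063), within a range of 0.00014 to 0.15 over 19 alternative analyses. Of 12 mature mTEC genes 5 rose and 0 fell, also adjusted over the list alone, without a call for the list (median 0.39, adjusted p = 0.15, and 0.0295 without RFP+ MHCIIlo replicate 1). The antigen regulator Fezf2 rose by 0.40 (SE 0.10) and the co-stimulatory ligand gene Cd80 by 1.02 (SE 0.12), while Cd40 was at 13.4 ± 5.38 against 17.9 ± 8.47 CPM (adjusted p = 0.18). The Aire difference above passed without RFP- MHCIIlo replicate 4 or RFP+ MHCIIlo replicate 1 (adjusted p = 0.029 and 0.021; range 0.0082 to 0.69 over 19 alternatives), and the Cd40 difference without RFP- MHCIIlo replicate 1 or RFP+ MHCIIlo replicate 4 (adjusted p = 0.027 and 0.050; range 0.0071 to 0.83 over 19 alternatives).

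Over all tested genes, 5677 were higher and 4452 lower in RFP+ MHCIIlo than in RFP- MHCIIlo, or 51.6% of those tested. Of these, 2908 were higher and 1737 lower by more than 2-fold. The p-values come from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Single libraries set the size of some differences. Pth was at 32.2 CPM in RFP+ MHCIIlo replicate 3 and at most 0.86 CPM in the others of that population (fitted log2 -9.82 without replicate 3, against levels near 0), and without 1 RFP+ MHCIIlo library each the log2 differences of Scn1a and Upk3b were -6.83 (replicate 4) and -6.13 (replicate 3). Scgb3a1, a secretoglobin gene, was at 117 CPM in RFP- MHCIIlo replicate 1 and fell by 4.02 (SE 0.87, adjusted p = 0.00043), but by 1.24 without that library, and limma-voom did not call it (adjusted p = 0.075; range 5.4e-30 to 0.075 over 18 alternatives).

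**Figure D2:**
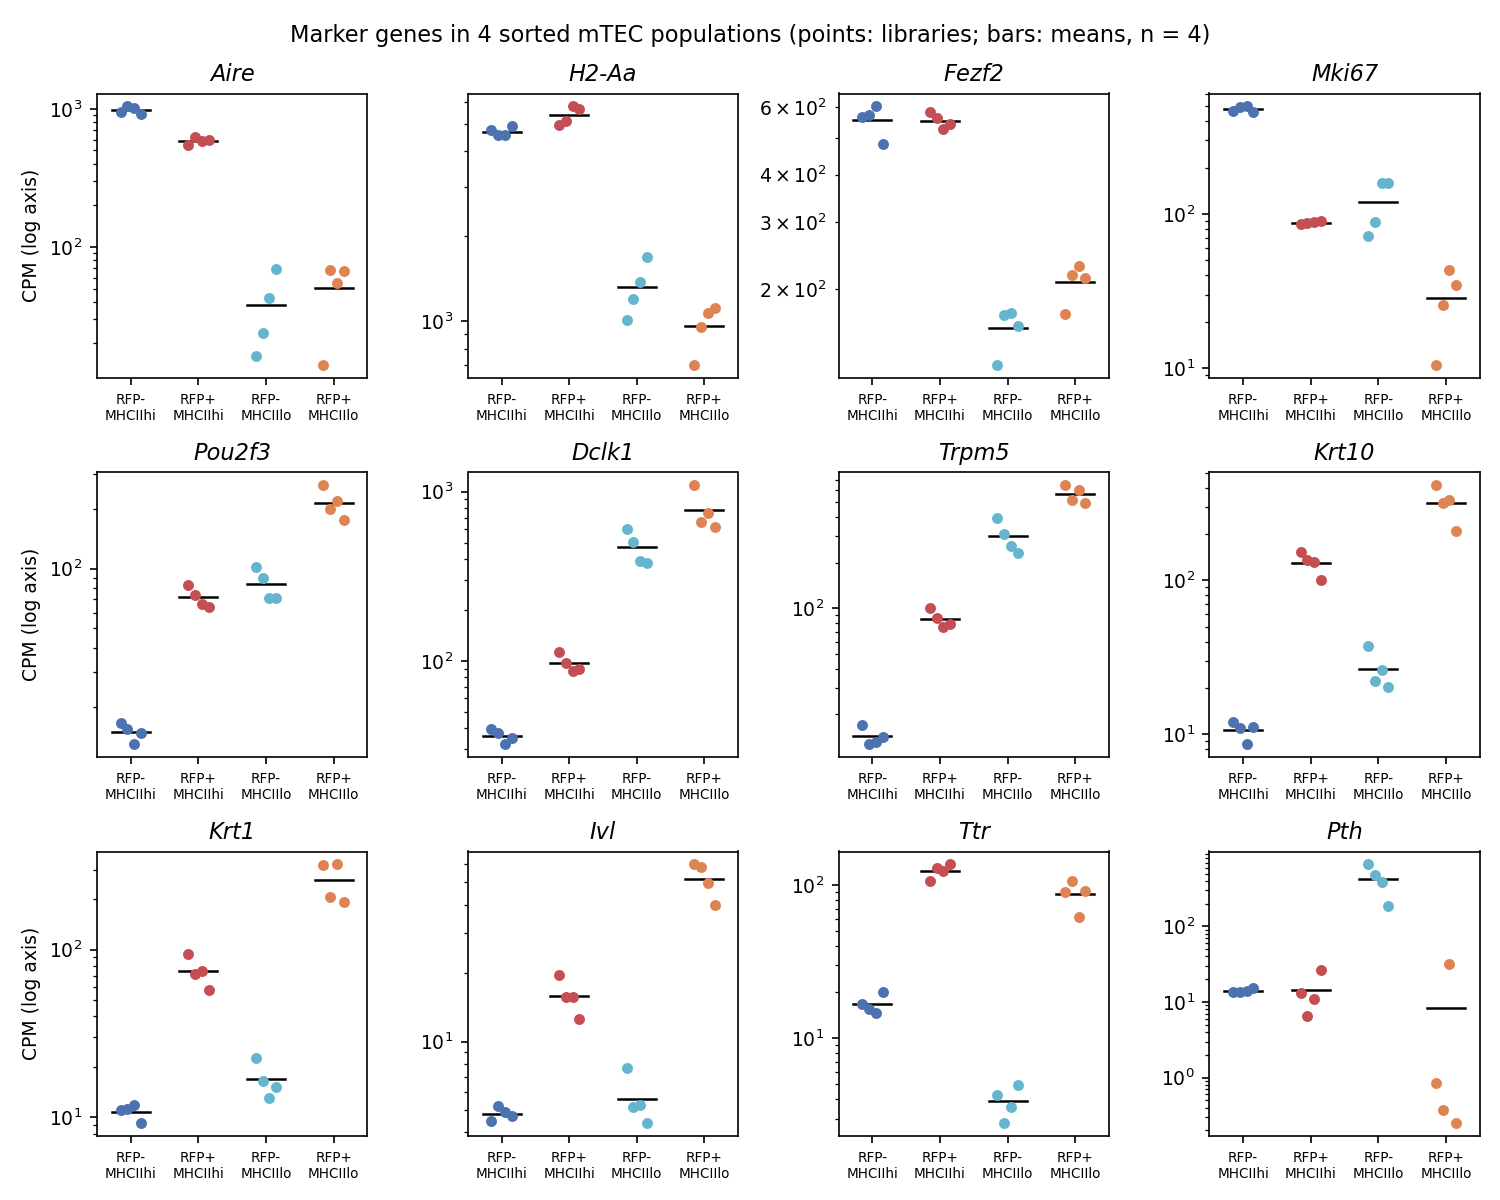
Normalised level (CPM, log axis) of 12 genes in each of the 16 libraries, by sorted population; points are libraries and bars are means of 4. Krt10, Krt1 and Ivl are highest in RFP+ MHCIIlo, Aire and H2-Aa are high in both MHCIIhi populations, and Pth is highest in RFP- MHCIIlo with 1 RFP+ MHCIIlo library at 32.2 CPM.

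Within the RFP+ cells, tuft cell genes were higher in MHCIIlo than in MHCIIhi cells by a median of 2.46 on the log2 scale, while MHC class II genes, Aire and most tested Aire-dependent antigens were far lower. This comparison asks what sets Aire-lineage cells with low MHC class II apart from those with high MHC class II. Dclk1 rose from 96.7 ± 11.8 to 779 ± 212 CPM (log2 3.01, SE 0.16, adjusted p = 5.9e-13) and Trpm5 from 85.3 ± 10.95 to 565 ± 69.8 CPM (2.73, SE 0.14, adjusted p = 3.3e-13). Aire fell from 587 ± 32.5 to 50.8 ± 25.4 CPM (-3.53, SE 0.35, adjusted p = 1.0e-08; SD, n = 4 each). Fgg, the gamma chain of fibrinogen made in liver, was at 24.2 ± 3.79 CPM in RFP+ MHCIIhi and 0.33 ± 0.27 CPM in RFP+ MHCIIlo.

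Of 32 tuft cell genes 29 rose and 0 fell (30 rose adjusted over the list alone; median 2.46, adjusted p = 1.6e-34; adjusted p = 0.032 with an estimated correlation). Pou2f3 rose by 1.58 (SE 0.12) and Il25 from 1.42 ± 0.41 to 10.7 ± 1.88 CPM. The adaptor gene Sh2d6 rose by 3.20 (SE 0.15), Rgs21, a regulator of taste cell G proteins, by 3.08 (SE 0.14) and Gnat3, the taste G protein gustducin, by 2.97 (SE 0.18). Cd177, Tspan6 and Itprid1 rose by 3.01 (SE 0.13), 2.97 (SE 0.15) and 2.97 (SE 0.20). All 28 tested bitter and other taste receptor genes rose, also adjusted over the list alone (median 3.05, adjusted p = 2.2e-15; adjusted p = 0.028 with an estimated correlation). Tas2r108 went from 3.69 ± 0.62 to 29.4 ± 5.23 CPM. These receptors are a family of similar genes, so reads shared between them cannot be excluded.

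Ciliated cell genes rose in 13 of 14 cases, also adjusted over the list alone (median 1.49, adjusted p = 2.9e-10; adjusted p = 0.028 with an estimated correlation), with Foxj1 up by 1.28 (SE 0.10). Of 9 microfold genes 8 rose and 1 fell, also adjusted over the list alone (median 1.05, adjusted p = 1.1e-06; adjusted p = 0.013 with an estimated correlation). Gp2 rose from 304 ± 25.3 to 1003 ± 42.4 CPM and Ccl20 by 1.09 (SE 0.14). Of 32 cornified genes 26 rose and 2 fell (27 and 2 adjusted over the list alone; median 1.25, adjusted p = 4.3e-10; adjusted p = 0.15 with an estimated correlation). Krt1, Krt10, Ivl and Lor rose by 1.81 (SE 0.16), 1.29 (SE 0.17), 1.71 (SE 0.15) and 1.83 (SE 0.28). Of 14 neuroendocrine genes 8 rose and 3 fell (9 and 3 adjusted over the list alone; median 0.88, adjusted p = 0.0099; adjusted p = 0.24 with an estimated correlation). The granule gene Chga rose by 0.88 (SE 0.21) and the synaptic gene Snap25 by 1.88 (SE 0.14).

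The gate marker list fell as a whole, with 10 of 10 MHC class II genes lower, also adjusted over the list alone (median -2.46, adjusted p = 3.2e-20; adjusted p = 0.028 with an estimated correlation). H2-Aa went from 5381 ± 396 to 961 ± 187 CPM and Cd74 fell by 1.88 (SE 0.16). All 12 mature mTEC genes fell, also adjusted over the list alone (median -2.12, adjusted p = 9.4e-14; adjusted p = 0.028 with an estimated correlation), with Fezf2, Cd80 and Cd40 down by 1.41 (SE 0.10), 2.23 (SE 0.10) and 3.18 (SE 0.24). Of 9 Aire-dependent antigens 8 fell and 0 rose, also adjusted over the list alone (median -2.77, adjusted p = 1.1e-07; adjusted p = 0.042 with an estimated correlation). Ins2 fell by 2.77 (SE 0.25) and Mucl2 by 1.70 (SE 0.15), whereas Tff3 was at 66.7 ± 20.6 against 52.6 ± 2.24 CPM (adjusted p = 0.12). Of 12 enterocyte and hepatocyte genes 7 fell and 3 rose (8 and 3 adjusted over the list alone; median -0.54, adjusted p = 0.031; adjusted p = 0.33 with an estimated correlation). Besides Fgg, the genes named for the largest decreases were Gstm3, Ceacam15, Cytl1, Crhbp, Idi2, Lta and Hba-x, at 21.2 to 50.9 CPM in RFP+ MHCIIhi and 0.75 to 1.87 CPM in RFP+ MHCIIlo. Hba-x is an embryonic globin gene, and Lta encodes lymphotoxin alpha.

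Of 16 chemokine genes 12 fell and 3 rose, also adjusted over the list alone (median -2.24, adjusted p = 7.5e-06; adjusted p = 0.21 with an estimated correlation). Ccl22, which attracts regulatory T cells, fell from 1006 ± 74.1 to 73.8 ± 12.0 CPM and Ccl25, which attracts thymocyte progenitors, by 2.41 (SE 0.16). Cxcl12 fell by 0.80 (SE 0.26, adjusted p = 0.011), a call that ended without RFP+ MHCIIhi replicate 4 (adjusted p = 0.080; range 1.9e-09 to 0.08 over 19 alternatives). Myeloid and dendritic cell genes, markers of cells the CD45 gate should remove, fell in 13 of 16 cases and rose in 0, also adjusted over the list alone (median -1.5, adjusted p = 1.3e-06; adjusted p = 0.14 with an estimated correlation). The lysozyme gene Lyz2 fell from 526 ± 11.1 to 137 ± 22.6 CPM. Immediate-early and heat shock genes, which respond to tissue dissociation, rose in 10 of 14 cases and fell in 2, also adjusted over the list alone (median 0.60, adjusted p = 0.00036; adjusted p = 0.24 with an estimated correlation). Fos rose by 1.07 (SE 0.10), and Hspa1a fell by 0.32 (SE 0.11, adjusted p = 0.014), a call lost without RFP+ MHCIIhi replicate 4 (adjusted p = 0.066; range 0.0003 to 0.12 over 19 alternatives).

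In total 5394 genes were higher and 5508 lower in RFP+ MHCIIlo than in RFP+ MHCIIhi, or 55.6% of those tested, by the same test. Decreases were larger: 702 genes fell and 35 rose by more than 8-fold. Cell cycle genes fell in 25 of 30 cases and rose in 1 (26 and 1 adjusted over the list alone; median -1.07, adjusted p = 0.00021; adjusted p = 0.47 with an estimated correlation). Without RFP+ MHCIIlo replicates 1 and 4, a choice made after seeing the data, 10280 genes were called against 10902, with 9142 in both.

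**Figure D3:**
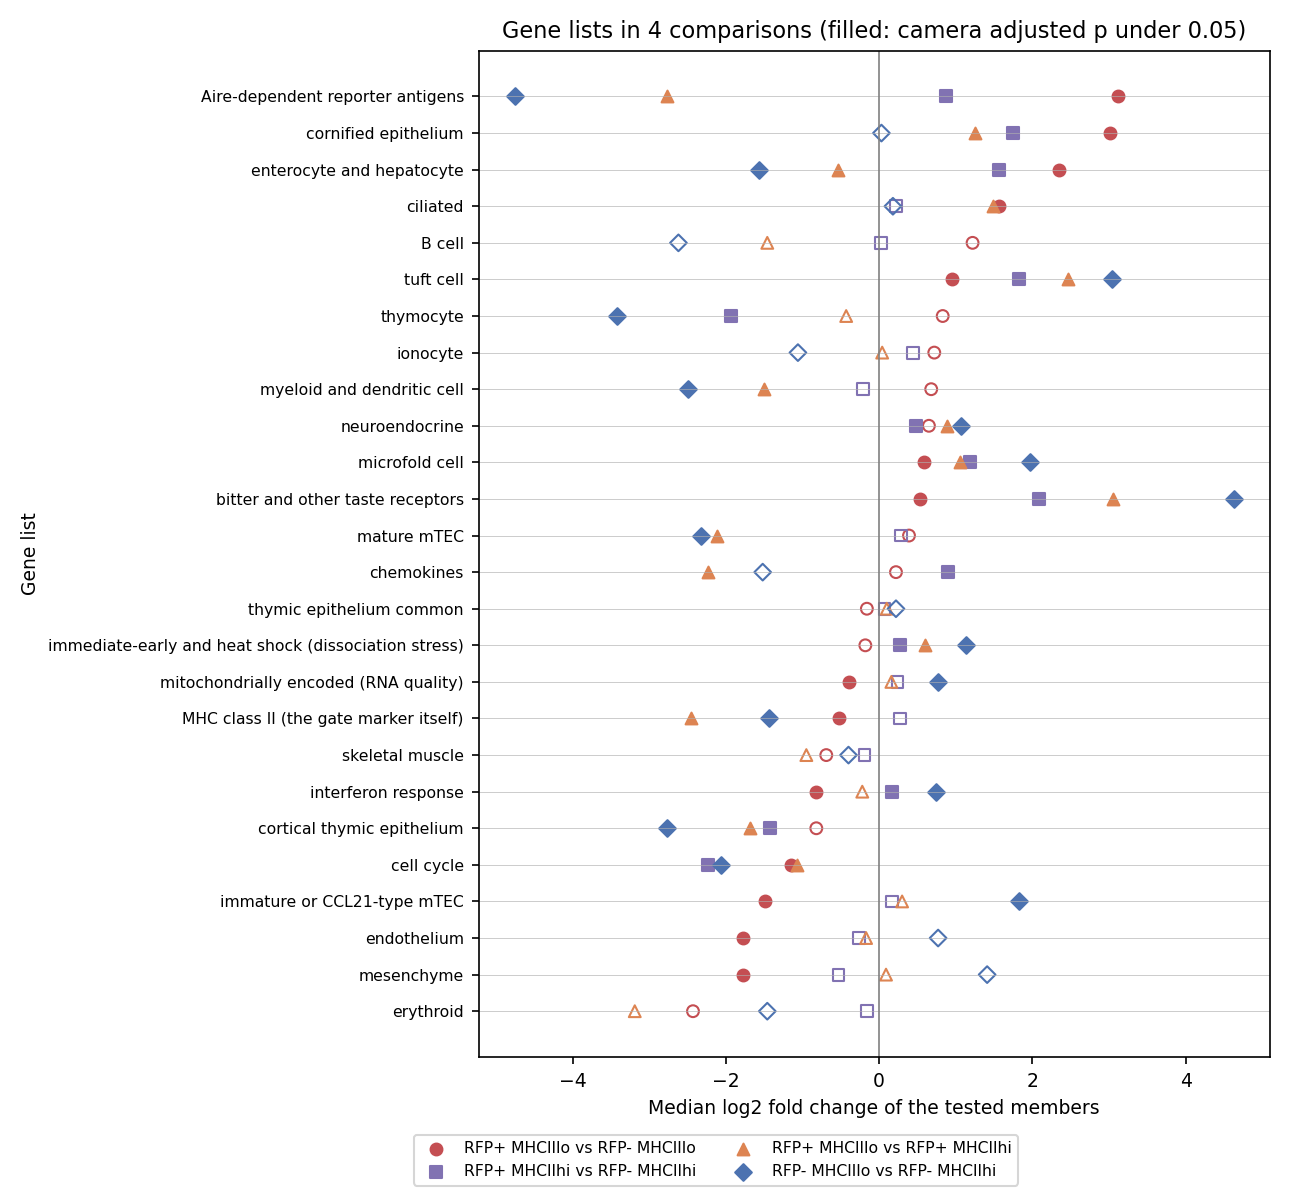
Median log2 fold change of the members of each gene list (horizontal axis) in the 4 comparisons of a pair of populations; filled symbols mark lists with a camera adjusted p under 0.05. Cornified and enterocyte and hepatocyte genes lie furthest to the right in RFP+ MHCIIlo against RFP- MHCIIlo among the lists, apart from Aire-dependent antigens at 3.12, and taste receptor and tuft cell genes in the comparisons of MHCIIlo with MHCIIhi.

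Among MHCIIhi cells, the RFP label went with fewer dividing-cell transcripts, less thymocyte and cortical epithelial RNA, and more keratinocyte, tuft and intestinal gene expression. The lists of dividing-cell, thymocyte and cortical genes did not pass when their correlation was taken from the data (adjusted p = 0.069, 0.28 and 0.21 with an estimated correlation). This comparison asks how labelled Aire-lineage cells differ from unlabelled cells at high MHC class II. Mki67 fell from 479 ± 21.02 to 88.0 ± 1.09 CPM (log2 -2.45, SE 0.25, adjusted p = 2.3e-08) and the cyclin gene Ccna2 from 83.0 ± 6.23 to 12.3 ± 1.40 CPM. Krt10 rose from 10.7 ± 1.46 to 130.2 ± 21.4 CPM (3.60, SE 0.20, adjusted p = 6.3e-13), and Pou2f3 from 15.0 ± 1.5 to 71.8 ± 8.31 CPM (2.25, SE 0.13, adjusted p = 2.7e-12; SD, n = 4 each). Aire was at 979 ± 56.1 CPM in RFP- MHCIIhi and 587 ± 32.5 CPM in RFP+ MHCIIhi (-0.74, SE 0.31, adjusted p = 0.057). The Aire call depended on the fit: it passed in 8 of 19 alternatives, with an adjusted p of 2.2e-09 in a fit of only these 8 libraries and a range of 2.2e-09 to 0.17.

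All 30 cell cycle genes fell, also adjusted over the list alone (median -2.24, adjusted p = 4.8e-29; adjusted p = 0.069 with an estimated correlation), with Top2a down by 2.62 (SE 0.20). Thymocyte genes fell in 15 of 16 cases and rose in 0, also adjusted over the list alone (median -1.94, adjusted p = 7.2e-07; adjusted p = 0.28 with an estimated correlation). Rag1, the recombinase gene of developing lymphocytes, fell from 137 ± 57.0 to 17.3 ± 6.18 CPM, and the T cell genes Cd3e and Cd8a fell by 1.97 (SE 0.32) and 2.52 (SE 0.29). The summed thymocyte genes were at 413, 470, 637 and 942 CPM in RFP- MHCIIhi replicates 1, 2, 3 and 4 and at 133 ± 38.2 CPM in RFP+ MHCIIhi. Cortical thymic epithelial genes fell in 8 of 9 cases (8 fell and 1 rose adjusted over the list alone; median -1.43, adjusted p = 1.5e-06; adjusted p = 0.21 with an estimated correlation). Psmb11, the thymoproteasome subunit gene of the cortex, fell from 194 ± 59.8 to 22.6 ± 11.6 CPM. The cortical protease gene Prss16 fell by 2.87 (SE 0.31) and Cxcl12 by 3.06 (SE 0.23).

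Of 32 cornified genes 30 rose and 1 fell, also adjusted over the list alone (median 1.75, adjusted p = 7.6e-29; adjusted p = 0.023 with an estimated correlation), including Krt1 (2.78, SE 0.18), Ivl (1.72, SE 0.16) and Lor (1.30, SE 0.31). Tuft cell genes rose in 28 of 32 cases and fell in 2 (29 and 2 adjusted over the list alone; median 1.83, adjusted p = 3.6e-30; adjusted p = 0.042 with an estimated correlation). Dclk1 rose by 1.42 (SE 0.16), Trpm5 by 2.57 (SE 0.15) and Il25 by 1.72 (SE 0.35). Taste receptor genes rose in 19 of 28 cases and fell in 0 (21 and 0 adjusted over the list alone; median 2.09, adjusted p = 0.00032; adjusted p = 0.22 with an estimated correlation). Of 12 enterocyte and hepatocyte genes 11 rose and 0 fell, also adjusted over the list alone (median 1.56, adjusted p = 1.5e-16; adjusted p = 0.0069 with an estimated correlation), with Saa3 up by 3.09 (SE 0.11) and Ttr by 2.88 (SE 0.14). Of 9 microfold genes 7 rose and 1 fell, also adjusted over the list alone (median 1.18, adjusted p = 3.0e-08; adjusted p = 0.0069 with an estimated correlation), with Gp2 up by 1.94 (SE 0.09) and Ccl20 by 1.73 (SE 0.14). Pigr, which carries antibodies across mucosal epithelia, rose from 24.5 ± 0.97 to 255 ± 19.3 CPM, Serpina7, a thyroid hormone carrier gene, by 3.5 (SE 0.21) and Dapl1 by 3.35 (SE 0.10). Klk1b16 rose by 3.40 (SE 0.19) but belongs to a cluster of near-identical kallikrein genes and is uncertain.

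Of 16 chemokine genes 10 rose and 3 fell, also adjusted over the list alone (median 0.90, adjusted p = 0.00051; adjusted p = 0.30 with an estimated correlation). Ccl22 rose from 199 ± 15.8 to 1006 ± 74.1 CPM, while Ccl25 fell by 0.84 (SE 0.15). Aire-dependent antigens rose in 5 of 9 cases and fell in 1, also adjusted over the list alone (median 0.87, adjusted p = 0.035; adjusted p = 0.36 with an estimated correlation), with Ins2 up by 1.18 (SE 0.21) and Mucl2 by 0.63 (SE 0.13). Dissociation stress genes rose in 9 of 14 cases and fell in 0, also adjusted over the list alone (median 0.27, adjusted p = 0.019; adjusted p = 0.39 with an estimated correlation). Fos rose by 0.76 (SE 0.10), and Hspa1a was at 204 ± 30.4 against 196 ± 19.6 CPM (adjusted p = 0.69, and -0.02 on the log2 scale without RFP+ MHCIIhi replicate 4). The B cell list, another marker of cells outside the gate, was not called (2 rose and 1 fell of 8, also adjusted over the list alone; median 0.02, adjusted p = 0.75), with Cd79a, a B cell receptor component, at 1.31 ± 0.44 against 1.79 ± 0.29 CPM. Ionocyte genes gave no call either (2 rose and 0 fell of 7, 4 and 1 adjusted over the list alone; median 0.44, adjusted p = 0.24).

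This contrast gave 4672 genes higher and 4158 lower, or 45% of those tested, with 1686 higher and 1156 lower by more than 2-fold. The balance turned with upper-quartile scaling, at 3998 higher and 5168 lower. RFP- MHCIIhi replicates 3 and 4 held the most thymocyte RNA. Without them, a choice made after seeing the data, 6749 genes were called, of which 6647 were among the 8830 found with all libraries.

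Among RFP- cells, the MHCIIlo population carried more tuft, basal epithelial and stress transcripts and far less antigen, cell cycle and thymocyte RNA than the MHCIIhi population. Of these lists the basal one passed in both tests, while tuft, stress, antigen, cell cycle and thymocyte genes gave adjusted p = 0.050, 0.13, 0.050, 0.30 and 0.36 with an estimated correlation, not under 0.05. This comparison gives the MHC class II difference in cells without the lineage mark, for reference to the labelled cells. Trpm5 rose from 14.3 ± 1.91 to 299 ± 71.3 CPM (log2 4.38, SE 0.16, adjusted p = 1.6e-16) and Krt5 from 189 ± 27.7 to 1342 ± 190.2 CPM (2.83, SE 0.11, adjusted p = 6.7e-16). Gas1, a growth arrest gene, rose from 5.21 ± 0.91 to 153 ± 12.3 CPM and Pth from 14.1 ± 0.94 to 427 ± 197 CPM (SD, n = 4 each). Aire fell from 979 ± 56.1 to 37.9 ± 23.5 CPM (-4.68, SE 0.37, adjusted p = 8.4e-11).

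Of 32 tuft cell genes 30 rose and 1 fell (31 and 1 adjusted over the list alone; median 3.04, adjusted p = 3.6e-30; adjusted p = 0.050 with an estimated correlation, not under 0.05). Pou2f3 rose by 2.47 (SE 0.14), Dclk1 by 3.69 (SE 0.17), Sh2d6 by 4.69 (SE 0.17) and Il25 by 3.76 (SE 0.31). All 28 taste receptor genes rose, also adjusted over the list alone (median 4.63, adjusted p = 9.9e-10; adjusted p = 0.056 with an estimated correlation). Ly6g6f, a surface protein gene, rose from 0.91 ± 0.24 to 25.4 ± 3.05 CPM. Of 11 genes of immature mTEC 9 rose and 1 fell, also adjusted over the list alone (median 1.83, adjusted p = 1.6e-08; adjusted p = 0.0025 with an estimated correlation), with Trp63 up by 1.83 (SE 0.08) and Krt14 by 2.08 (SE 0.11). Microfold genes rose in 7 of 9 cases and fell in 1, also adjusted over the list alone (median 1.97, adjusted p = 7.5e-07; adjusted p = 0.010 with an estimated correlation), Gp2 by 2.95 (SE 0.10) and Ccl20 by 1.97 (SE 0.14). Interferon genes rose in 7 of 11 cases and fell in 3, also adjusted over the list alone (median 0.74, adjusted p = 0.0012; adjusted p = 0.21 with an estimated correlation), Isg15 by 2.40 (SE 0.11). Neuroendocrine genes rose in 9 of 14 cases and fell in 3, also adjusted over the list alone (median 1.07, adjusted p = 0.023; adjusted p = 0.31 with an estimated correlation), Chga by 3.13 (SE 0.22) and Snap25 by 1.51 (SE 0.15).

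All 14 dissociation stress genes rose, also adjusted over the list alone (median 1.13, adjusted p = 4.1e-07; adjusted p = 0.13 with an estimated correlation). Fos rose by 1.96 (SE 0.10) and Hspa1a by 0.30 (SE 0.11, adjusted p = 0.017), the latter lost without RFP- MHCIIhi replicate 3 or 4 (adjusted p = 0.058 and 0.063; range 0.0067 to 0.28 over 19 alternatives). All 7 tested mitochondrially encoded genes rose as well, also adjusted over the list alone (median 0.77, adjusted p = 0.027; adjusted p = 0.40 with an estimated correlation). Mesenchymal genes rose in 7 of 10 cases and fell in 1 (7 and 2 adjusted over the list alone; median 1.41, adjusted p = 0.063), a list that passed without RFP- MHCIIlo replicate 2 or 4 (adjusted p = 0.0268 and 0.0385). Dcn rose by 2.90 (SE 0.21), and Col1a1 was at 58.1 ± 31.4 against 44.3 ± 3.97 CPM (adjusted p = 0.25). Endothelial genes rose in 5 of 9 cases and fell in 1, also adjusted over the list alone, without a call (median 0.77, adjusted p = 0.24), with Pecam1 at 11.7 ± 0.74 against 10.9 ± 2.74 CPM. The erythroid list was not called (0 rose and 3 fell of 4, also adjusted over the list alone; median -1.46, adjusted p = 0.35), with Hbb-bs at 1.95 ± 1.52 against 1.78 ± 0.19 CPM. The uncalled differences of Col1a1, Pecam1 and Hbb-bs turned negative when 1 library was left out, at -0.02 (without RFP- MHCIIlo replicate 3), -0.02 (without RFP- MHCIIhi replicate 1) and -0.53 (without RFP- MHCIIlo replicate 1).

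Lower in RFP- MHCIIlo were all 10 genes of the gate marker list, also adjusted over the list alone (median -1.44, adjusted p = 6.4e-06; adjusted p = 0.22 with an estimated correlation), with H2-Aa down by 1.83 (SE 0.14) and Cd74 by 1.39 (SE 0.16). Mature mTEC genes fell in 11 of 12 cases, also adjusted over the list alone (median -2.33, adjusted p = 1.5e-07; adjusted p = 0.15 with an estimated correlation), Fezf2 by 1.81 (SE 0.10), Cd80 by 2.63 (SE 0.11) and Cd40 by 3.20 (SE 0.23). All 9 Aire-dependent antigens fell, also adjusted over the list alone (median -4.76, adjusted p = 2.5e-07; adjusted p = 0.050 with an estimated correlation, not under 0.05). Of 12 enterocyte and hepatocyte genes 10 fell and 2 rose, also adjusted over the list alone (median -1.57, adjusted p = 7.1e-05; adjusted p = 0.13 with an estimated correlation). The largest decreases were in tissue genes that were almost silent in RFP- MHCIIlo. Rln3, a relaxin gene, went from 52.2 ± 5.66 to 0.26 ± 0.46 CPM, Myoc, the myocilin gene, from 20.1 ± 1.09 to 0.11 ± 0.16 CPM, and the milk casein gene Csn1s2a from 36.4 ± 2.00 to 0.33 ± 0.23 CPM. Mt4, an epithelial metallothionein, went from 46.9 ± 2.90 to 0.43 ± 0.36 CPM. Levels below 1 CPM rest on few reads, and any fitted log2 value against them depends on the prior count and is no bound.

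Cell cycle genes fell in 30 of 30 cases, also adjusted over the list alone (median -2.06, adjusted p = 6.4e-09; adjusted p = 0.30 with an estimated correlation), Mki67 by 2.00 (SE 0.25). Cortical genes fell in 9 of 9 cases, also adjusted over the list alone (median -2.77, adjusted p = 2.8e-05; adjusted p = 0.26 with an estimated correlation), Psmb11 by 3.39 (SE 0.28) and Prss16 by 3.20 (SE 0.32). Thymocyte genes fell in 15 of 16 cases, also adjusted over the list alone (median -3.42, adjusted p = 4.7e-05; adjusted p = 0.36 with an estimated correlation), Rag1 by 3.79 (SE 0.34). Myeloid genes fell in 16 of 16 cases, also adjusted over the list alone (median -2.49, adjusted p = 7.5e-06; adjusted p = 0.21 with an estimated correlation), Lyz2 by 2.25 (SE 0.13) and C1qa, a macrophage complement gene, by 1.77 (SE 0.45). Genes common to thymic epithelium gave no call (4 rose and 1 fell of 9, also adjusted over the list alone; median 0.22, adjusted p = 0.24), with Epcam up by 0.45 (SE 0.08) and Foxn1, the thymic epithelial master regulator, down by 1.39 (SE 0.08). Skeletal muscle genes rose in 5 and fell in 4 of 11 cases, also adjusted over the list alone, with a median of -0.40 and a mean of opposite sign (adjusted p = 0.62). The muscle regulator Myog rose by 1.57 (SE 0.20), and the creatine kinase gene Ckm was at 2.91 ± 1.64 against 3.78 ± 0.74 CPM (adjusted p = 0.30).

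This was the largest contrast, with 6564 genes higher and 6989 lower (69.1% of those tested) and 1607 genes lower by more than 8-fold. It shared no library with the same gate comparison in RFP+ cells. Across the 19617 genes, which are not independent replicates, the log2 changes of the pair correlated with Pearson's r of 0.784 and Spearman's rho of 0.733. Genes higher in both numbered 3912 and genes lower in both 4382, where independent lists of these sizes would share 1805 and 1962. The RFP differences in the MHCIIlo and MHCIIhi gates correlated less, at r of 0.373 and rho of 0.377, with 2912 genes higher in both (1352 if independent) and 1959 lower in both (944 if independent).

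The effect of the RFP label differed between the MHC class II gates for 6693 genes, with the signed log2 RFP change in MHCIIlo minus that in MHCIIhi positive for 3438 and negative for 3255. This test asks whether the lineage mark goes with the same change at low and high MHC class II. Endou, an endoribonuclease gene, was higher with RFP in MHCIIlo (21.2 ± 5.26 against 1.88 ± 0.28 CPM) and lower in MHCIIhi (7.15 ± 1.55 against 17.2 ± 7.28 CPM), a difference of 4.75 on the log2 scale (SE 0.38, adjusted p = 1.3e-09). Krt5 changed in opposite directions, with a difference of -2.02 (SE 0.15, adjusted p = 4.1e-10). Krt10 rose alike in both gates, with a difference of 0.01 (SE 0.28, adjusted p = 0.99) that turned slightly negative without single libraries, furthest to -0.14 without RFP+ MHCIIlo replicate 1.

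The RFP change in MHCIIlo minus that in MHCIIhi was negative for 10 of 11 immature mTEC genes and positive for 0, also adjusted over the list alone (median -1.02, adjusted p = 4.2e-13; adjusted p = 0.0009 with an estimated correlation), including Trp63 (-1.86, SE 0.12). As a list these genes fell with RFP in MHCIIlo (median -1.49) and were not called in MHCIIhi (median 0.17). For interferon genes 9 of 11 values were negative and 0 positive, also adjusted over the list alone (median -1.62, adjusted p = 6.4e-14; adjusted p = 0.010 with an estimated correlation), including Isg15 (-2.01, SE 0.16), with list medians of -0.82 in MHCIIlo and 0.17 in MHCIIhi. For tuft cell genes 20 of 32 differences were negative and 0 positive (23 and 1 adjusted over the list alone; median -0.77, adjusted p = 6.2e-09; adjusted p = 0.26 with an estimated correlation). Trpm5 gave -1.65 (SE 0.19), Pou2f3 -0.90 (SE 0.18) and Dclk1 -0.68 (SE 0.22, adjusted p = 0.017), while Il25 gave -0.84 (adjusted p = 0.12, and -1.29 with adjusted p = 0.022 without RFP- MHCIIhi replicate 3). Dclk1 was not called by DESeq2 (adjusted p = 0.060; range 8.3e-06 to 0.091 over 26 alternatives).

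For cornified genes 20 of 32 values were positive and 2 negative (21 and 3 adjusted over the list alone; median 1.05, adjusted p = 1.9e-09; adjusted p = 0.17 with an estimated correlation), among them Krt1 (1.18, SE 0.25), Ivl (1.5, SE 0.23) and Lor (2.37, SE 0.46, and 3.13 without RFP- MHCIIlo replicate 1). Ciliated genes gave 9 positive and 0 negative values of 14 (11 and 1 adjusted over the list alone; median 0.89, adjusted p = 1.7e-05; adjusted p = 0.14 with an estimated correlation), with Foxj1 at 1.11 (SE 0.14). Thymocyte genes gave 14 positive and 0 negative values of 16, also adjusted over the list alone (median 2.90, adjusted p = 6.0e-09; adjusted p = 0.22 with an estimated correlation), Cd8b1 at 3.79 (SE 0.48) and Rag1 at 3.60 (SE 0.47). Those thymocyte values combine list medians of -1.94 in MHCIIhi and 0.83 in MHCIIlo, the latter without a call, and rest on high levels in RFP- MHCIIhi, where Cd8b1 was at 33.7 ± 14.3 CPM against 2.09 to 5.31 CPM elsewhere. Mucl2 and the kallikrein gene Klk5 were at 0.38 ± 0.21 and 0.49 ± 0.34 CPM in RFP- MHCIIlo and at 10.4 ± 1.66 and 5.33 ± 3.19 CPM in RFP+ MHCIIlo (adjusted p = 7.6e-10 and 2.3e-06 for the difference of effects). The strongest negative values were Pth at -5.67 (SE 0.91, and -9.82 without RFP+ MHCIIlo replicate 3), Cav1 at -4.40 (SE 0.40), Scgb3a1 at -4.62 (SE 1.18, and -1.83 without RFP- MHCIIlo replicate 1) and the antibody gene Ighg2b at -5.37 (SE 1.28). limma-voom called neither Scgb3a1 nor Ighg2b (adjusted p = 0.092 and 0.21; ranges 1.8e-22 to 0.092 over 25 alternatives and 5.2e-24 to 0.21 over 26), and the Ighg2b value was -4.56 without RFP+ MHCIIhi replicate 4, -4.59 without RFP- MHCIIlo replicate 3, -5.97 without RFP+ MHCIIlo replicate 3 and -6.03 without RFP- MHCIIhi replicate 2.

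Each population also had genes of its own, higher than in each of the other 3 by more than 2-fold with an adjusted p under 0.05 each time. They numbered 651 in RFP+ MHCIIlo, 252 in RFP+ MHCIIhi, 845 in RFP- MHCIIlo and 675 in RFP- MHCIIhi. With the filter of 5 CPM in 4 libraries RFP+ MHCIIlo had 409 and RFP- MHCIIhi 402. The 6 named for RFP+ MHCIIlo were Tmem212, Lypd5, Spata18, Fam183b, Abca12 and Atp6v1c2. Abca12, the lipid transporter of the epidermal barrier, was at 67.6 ± 7.91 CPM against 3.97 to 17.3 CPM in the other populations (SD, n = 4). Lypd5 was at 29.0 ± 6.44 against 2.11 to 5.29 CPM, Spata18 at 32.9 ± 2.46 against 4.28 to 7.78 CPM and Tmem212 at 36.0 ± 14.9 against 1.00 to 8.89 CPM. Fam183b, a gene of motile cilia, was at 40.1 ± 3.53 against 4.87 to 10.1 CPM.

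The number of genes detected was compared after thinning each library to 7929533 reads, the smallest total, because mTEC are known for the breadth of their transcription. Only the total was matched: protein-coding genes took 52.6 ± 2.23% of reads in RFP- MHCIIlo, 59.0 ± 2.15% in RFP+ MHCIIlo, 62.1 ± 1.76% in RFP- MHCIIhi and 63.8 ± 1.25% in RFP+ MHCIIhi (SD, n = 4 each), so RFP- MHCIIlo had the fewest reads left for them. Genes with at least 5 reads numbered 19408 ± 255 in RFP- MHCIIhi, 19056 ± 92.0 in RFP+ MHCIIhi, 18206 ± 633 in RFP+ MHCIIlo and 17222 ± 116 in RFP- MHCIIlo (SD, n = 4 each). RFP+ MHCIIlo held 983.5 more genes than RFP- MHCIIlo, the RFP+ MHCIIlo libraries spanning 17421 to 18930 (two-sided exact permutation test, p = 0.0286, adjusted p = 0.0571 over 4 comparisons). The other differences were -850.8 for RFP+ MHCIIlo against RFP+ MHCIIhi, -351.5 for RFP+ MHCIIhi against RFP- MHCIIhi and -2185.8 for RFP- MHCIIlo against RFP- MHCIIhi (exact permutation p = 0.0571, 0.0571 and 0.0286, adjusted p = 0.0571 each). None passed at 0.05 after adjustment, and 0.0286 is the smallest p that 70 arrangements of 8 libraries allow. At least 20 reads per gene in place of 5 gave an adjusted exact permutation p of 0.0286 for each of the 4 differences, in the same directions. With at least 1 read none of the 4 passed, again in the same directions.

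**Figure D4:**
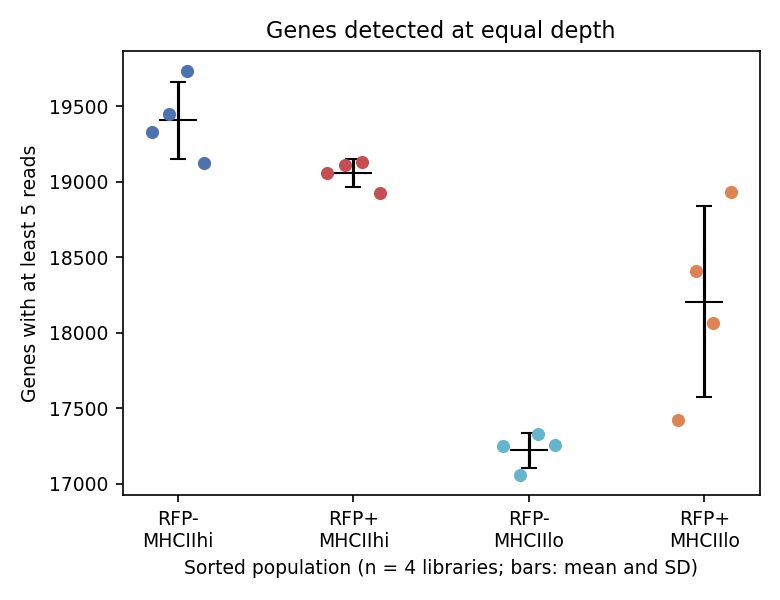
Genes with at least 5 reads after thinning each library to 7929533 reads (vertical axis, number of genes, axis not starting at 0), by sorted population; points are libraries and bars show mean and SD. RFP- MHCIIlo lies lowest at 17222 ± 116, and the RFP+ MHCIIlo libraries spread from 17421 to 18930.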

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

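Of the tests in this part, those of mesenchymal cells and of fewer sorted cells were chosen only after the result was seen, as was leaving out pairs of libraries. Libraries far from the other 3 of their population were sought for the named genes and summed lists, as the gap of the highest or lowest library to its nearest neighbour over the range of the population. Of 512 tests 27 passed, or about 1 in 20, which is the 5% that chance gives. Aire was lowest in RFP+ MHCIIlo replicate 1 (0.858, at 3.85 against a median of 6.08 log2 CPM), as were Cav1 (0.949) and the summed mature mTEC genes (0.928), and Gnat3 was highest there (0.832). Pth was highest in RFP+ MHCIIlo replicate 3 (0.842, at 5.03 against -0.20) and in RFP- MHCIIhi replicate 4 (0.836). RFP+ MHCIIlo replicate 3 also had the highest Chga (0.853) and the lowest ionocyte sum (0.835). In RFP- MHCIIlo replicate 1, Scgb3a1 (0.849, at 6.87 against 2.35), Krt77 (0.962), Lor (0.909) and the cornified sum (0.836) were highest and Ccl20 lowest (0.959). RFP- MHCIIlo replicate 2 had the lowest C1qa (0.926) and the highest Endou (0.831), and replicate 4 the highest Rln3 (0.845). In RFP+ MHCIIhi, replicate 4 had the highest Idi2 (0.846), Ighg2b (0.835) and thymocyte sum (0.932) and the lowest Cav1 (0.875). Its replicate 1 had the highest Krt5 (0.883) and the lowest Top2a (0.92), and its replicate 2 the lowest Cytl1 (0.844) and the highest microfold sum (0.83). In RFP- MHCIIhi, Rgs21 was lowest in replicate 2 (0.845), Tspan6 lowest in replicate 3 (0.902) and the ciliated sum highest in replicate 1 (0.851).

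The RFP effect differed between the MHC class II gates, by the test of the difference itself, for 72 of 99 named genes, with n = 4 libraries per population, and for 3438 of all genes upwards and 3255 downwards. Values are the RFP effect in MHCIIlo minus that in MHCIIhi on the log2 scale. For genes below 1 CPM in a population (Rln3, Csn1s2a, Mt4, Mucl2, Klk5, Hba-x, Ins2, Cytl1, Ceacam15, Scn1a, Ly6g6f, Tas2r108 and Ighg2b among them) they depend on the prior count and are no bounds. Positive values above 3 were those of Endou (4.75), Mucl2 (4.12), Cd8b1 (3.79), Klk5 (3.69), Cd8a (3.63), Rag1 (3.60), Rln3 (3.21) and Cd3e (3.12). They were followed by Tff3 (2.89), Krt77 (2.86), Mt4 (2.85), Klk13 (2.72), Csn1s2a (2.38), Lor (2.37), Lypd5 (2.14) and Hba-x (2.02). Values between 1.4 and 2 were those of Ins2 (1.99), Gad1 (1.75), Psmb11 (1.70), Prss16 (1.69), Cytl1 (1.68), Ttr (1.60), Ceacam15 (1.58), Spata18 (1.56), Ivl (1.5), Ccl25 (1.41) and Top2a (1.40). Smaller ones were those of Ear1 (1.35), Abca12 (1.23), Fam183b (1.23), Krt1 (1.18), Ccna2 (1.14), Foxj1 (1.11), Atp6v1c2 (1.10), Cyp2b19 (1.09) and Saa3 (1.00). For Cd80 (0.40) and Fezf2 (0.40) the call ended when single libraries were left out, such as RFP+ MHCIIlo replicate 3 (adjusted p = 0.19 and 0.092).

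Negative values beyond -3 were those of Pth (-5.67), Ighg2b (-5.37), Scgb3a1 (-4.62), Cav1 (-4.40), Igfbp6 (-4.29), Upk3b (-4.05), Fmod (-3.81), Prelp (-3.65) and Gas1 (-3.40). Next came Scn1a (-2.52), Crp (-2.44), Chga (-2.26), Ly6g6f (-2.13), Krt5 (-2.02) and Isg15 (-2.01). Trp63 (-1.86), Tas2r108 (-1.83), Pigr (-1.78), Gnat3 (-1.68), Trpm5 (-1.65), Pecam1 (-1.52), Sh2d6 (-1.48), Rgs21 (-1.46) and Gp2 (-1.23) followed. The smallest were Serpina7 (-0.96), Itprid1 (-0.94), Pou2f3 (-0.90), Fos (-0.89), Ccl20 (-0.88), Dclk1 (-0.68), H2-Aa (-0.65), Hspa1a (-0.62), Cd177 (-0.58) and Dapl1 (-0.58). Without RFP+ MHCIIlo replicate 3 the Pth value was -9.82, and without RFP- MHCIIlo replicate 1 the Scgb3a1 and Lor values were -1.83 and 3.13. The MHCIIlo changes behind the Scn1a and Upk3b values likewise grew without RFP+ MHCIIlo replicate 4 and replicate 3, as given above. The Ins2 value was 3.06 without RFP- MHCIIlo replicate 4, and the Ighg2b value ran from -4.56 to -6.03 without single libraries, as given above.

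Pth, Upk3b and the matrix genes Prelp and Fmod stood out in RFP- MHCIIlo, with Pth at 427 ± 197 CPM. For parathyroid cells in that sort, the median over 10 parathyroid genes of the smallest log2 difference from the 3 other populations was -0.35 (95% bootstrap interval -1.23 to 0.28), and 1 of the 10, Chga, was higher there than in each other population at an adjusted p under 0.05, Casr lying at 31.4 CPM in RFP- MHCIIlo and 42.2 CPM in RFP+ MHCIIlo. This met the bound written beforehand against such cells, but that bound was set aside after the result was seen, because 8 of the 10 genes were at 1 CPM or more in RFP+ MHCIIhi and so much baseline transcription could hide a small share of parathyroid cells. Mesothelial cells (1.42 over 9 genes, -0.04 to 2.92, 6 passing that criterion, 8 at 1 CPM or more in RFP+ MHCIIhi, Msln at 352 CPM in RFP- MHCIIlo and 362 CPM in RFP+ MHCIIlo) and mesenchymal cells (1.12 over 10 genes, 0.39 to 2.16, 6 passing it, all 10 at 1 CPM or more in RFP+ MHCIIhi, Dcn at 376 CPM) stay open as well, although the EPCAM gate should remove mesenchyme. Transcription of these genes by unlabelled MHCIIlo epithelial cells was not tested and stays open beside them.

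Thymocyte and cortical epithelial transcripts were high in RFP- MHCIIhi, with Psmb11 at 194 ± 59.8 CPM. Over 14 further thymocyte genes the median of the smallest log2 difference from the 3 other populations was 1.24 (1.04 to 1.65), 13 of 14 were higher there than in each other population at an adjusted p under 0.05, and Tcf7, Satb1 and Trbc2 reached 213, 169 and 77.3 CPM, which is consistent with carried thymocyte RNA even though the CD45 gate should remove thymocytes and all 14 were at 1 CPM or more in RFP+ MHCIIhi. For cortical epithelial cells, 6 further genes gave -0.51 (-2.06 to 0.81), and 2 of the 6 passed the same criterion. That met the bound written beforehand against cortical cells, and it was set aside after the result was seen, because all 6 are at 1 CPM or more in RFP+ MHCIIhi and Ackr4, Slc46a2 and Il7 were highest in RFP- MHCIIlo (81.6, 140.8 and 148.5 CPM), a gate that equally lacks a cortical marker. Cortical cells and cortical transcription in unlabelled mTEC could therefore not be told apart, and the latter was not tested.

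RFP+ MHCIIlo, with 651 genes of its own, was also the population with the fewest sorted cells and the most reads resembling ribosomal RNA. A trend with GC content and gene length was removed from each library. The median of the smallest log2 difference over the 651 genes was then 1.36 (1.32 to 1.38) against 1.33 before. Of these genes 639 had both measures, and 552 of the 651 kept their call. With the share of reads resembling ribosomal RNA as a covariate, the median was 1.33 (1.29 to 1.37) and 502 genes kept their call. Neither correction removed most of the calls. The medians decide little further, because the genes were chosen in the same data for a difference above 1. Their intervals resample genes and not libraries, and the share of such reads partly goes with the population, so neither cause is excluded. Fewer sorted cells as input stays open, since 0 libraries of the other populations came from as few cells (at least 80500 against at most 20500). It cannot be told apart from a lineage and MHC class II state of these cells, the biological difference that the design names.

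Other groupings of the libraries gave fewer genes, which does not exclude chance as the source. Such groupings mix the populations, which widens the spread within groups and lowers the count. Among all 35 splits of the 8 libraries of a contrast, 1 gave as many genes, the real split. It gave 10129 genes for RFP+ MHCIIlo against RFP- MHCIIlo (highest other 201), 10902 against RFP+ MHCIIhi (0), 8830 for RFP+ MHCIIhi against RFP- MHCIIhi (0) and 13553 for RFP- MHCIIlo against RFP- MHCIIhi (1). For the difference of RFP effects the real grouping gave 6693 and the highest other of 100 partitions of the 16 libraries 3123. For the genes of a population's own the real grouping gave 675, 845, 252 and 651 in RFP- MHCIIhi, RFP- MHCIIlo, RFP+ MHCIIhi and RFP+ MHCIIlo, and the highest other of 100 partitions gave 0 each time.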

How the results depend on the processing

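In this part, leaving out genes that resemble ribosomal RNA, RFP+ MHCIIlo replicates 1 and 4, or RFP- MHCIIhi replicates 3 and 4 was chosen after the data were seen. No called named gene changed direction under an alternative. No called list did either with median-ratio scaling, the block, an estimated correlation, fry or each library left out, the alternatives run for lists. Other called genes were not compared for direction in this way. Uncalled differences near 0, such as those of Col1a1, Pecam1 and Hbb-bs given above, did change sign. The counts of changed genes stayed within 1.5 times their values under median-ratio and upper-quartile scaling, no filter, the 5 CPM filter, DESeq2, limma-voom, the block, fits of 8 libraries and each library left out. Requiring a fold beyond 2 lowered them by construction, to 1410 higher and 936 lower genes for RFP+ MHCIIlo against RFP- MHCIIlo, 924 and 1990 for RFP+ MHCIIlo against RFP+ MHCIIhi, 840 and 357 for RFP+ MHCIIhi against RFP- MHCIIhi and 2015 and 3424 for RFP- MHCIIlo against RFP- MHCIIhi. The 5 CPM filter, which tested 13563 genes, lowered the genes of a population's own to 402 in RFP- MHCIIhi and 409 in RFP+ MHCIIlo. Of the 75 list calls 19 passed with the correlation estimated from the data, an alternative built to allow for correlated genes, and fry made 107. Detection with at least 20 reads passed in all comparisons (540.5, -677.5, -288.8 and -1506.8 in the order above, adjusted exact permutation p = 0.0286 each), and at 1 CPM in 3 (902.2, -858.5 and -1974.2, adjusted exact permutation p = 0.0381 each, without RFP+ MHCIIhi against RFP- MHCIIhi). With at least 1 read the 4 differences kept their direction and none passed. Libraries then held 23073 to 26585 genes in RFP+ MHCIIlo and 23668 to 24789 in RFP- MHCIIlo, so these overlapped. All these tests treated the libraries as unpaired. Why the calls differed by threshold was not tested.

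With each library left out in turn, list calls numbered 74 to 80. Higher and lower genes ranged over 5168 to 5860 and 4021 to 4624 for RFP+ MHCIIlo against RFP- MHCIIlo, 4834 to 5381 and 5182 to 5875 against RFP+ MHCIIhi, 4200 to 4399 and 3612 to 3829 for RFP+ MHCIIhi against RFP- MHCIIhi, and 6200 to 6465 and 6710 to 7005 for RFP- MHCIIlo against RFP- MHCIIhi. The difference of RFP effects gave 2883 to 3754 and 2993 to 3433. Genes of a population's own numbered 616 to 750 in RFP- MHCIIhi, 782 to 888 in RFP- MHCIIlo, 239 to 283 in RFP+ MHCIIhi and 615 to 700 in RFP+ MHCIIlo. Detection differences ranged over 742 to 1245, -1092.2 to -589.2, -446.4 to -242.8 and -2280.7 to -2077. For the named genes 2694 of 2824 such values were the same in call and direction, 57 lost and 23 gained a call, and 50 moved otherwise. DESeq2 kept 291 of 296 and limma-voom 282 of 298.

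Without RFP+ MHCIIlo replicates 1 and 4, 9589 genes were called against RFP- MHCIIlo, 8556 of them among the 10129, and RFP+ MHCIIlo had 645 genes of its own. Without RFP- MHCIIhi replicates 3 and 4, 12165 genes were called for RFP- MHCIIlo against RFP- MHCIIhi, 11820 of them among the 13553, and RFP- MHCIIhi had 516 genes of its own. Without genes that resemble ribosomal RNA the first contrast gave 5689 higher and 4422 lower genes. Upper-quartile scaling moved the median of all genes to -0.118 for RFP- MHCIIlo against RFP- MHCIIhi, -0.1 for RFP+ MHCIIhi against RFP- MHCIIhi and 0.118 for the difference of RFP effects, from -0.004, -0.016 and 0.039, so small changes there are relative to the scaling. With it the share of called genes that were higher in RFP+ MHCIIhi than in RFP- MHCIIhi turned from 52.9 to 43.6%. The balance also turned with the 5 CPM filter, to 4334 higher and 3950 lower genes for RFP+ MHCIIlo against RFP+ MHCIIhi and 5003 and 4847 for RFP- MHCIIlo against RFP- MHCIIhi. For the difference of RFP effects it turned with limma-voom (3169 and 3304) and without single libraries, such as RFP- MHCIIhi replicate 1 (2883 and 3184). With upper-quartile scaling 59.8% of the called differences were positive, so which direction prevails there depended on the processing. A replicate block moved counts little, as to 10223 with 9962 shared in the first contrast. The numbers were not taken to pair the samples, though the best match of a library had its own number in 35 of 48 comparisons (same-number median 0.057, others -0.017). The block changed 5 list calls. In the first contrast the endothelial list lost its call (adjusted p = 0.0662), and the cortical (0.00713, from 0.069) and skeletal muscle lists (0.0342, from 0.051) gained one, both downwards. The neuroendocrine list of RFP+ MHCIIhi against RFP- MHCIIhi lost its call (0.0635, from 0.041), and the mesenchymal list of RFP- MHCIIlo against RFP- MHCIIhi gained one (0.0498). Depth limits genes near 0, where levels rest on few reads, and RFP+ MHCIIlo had the lowest mean total, 9.97 M.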

Other observations

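The tests of neighbouring genes below were planned, while the genes and regions named in this part were chosen after their values were seen. Genes of a population's own tended to lie beside each other in the genome. In RFP+ MHCIIlo 202 of 639 placed genes had another within 3 tested genes (median of 10000 random sets 115, highest 163), in RFP- MHCIIlo 327 of 836 (192.5 and 266), in RFP+ MHCIIhi 82 of 252 (18 and 43) and in RFP- MHCIIhi 230 of 673 (127 and 176). The permutation p was 1e-04 each time, the smallest that 10000 random sets can give. Tandem gene families may account for part of this, because runs such as the 7 Klk1b genes of RFP+ MHCIIhi are paralogs that can share reads, and overlapping or antisense genes count as neighbours too.

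In RFP+ MHCIIlo a run on chromosome 7 (30751471 to 30914873) held the epidermal genes Sbsn, Dmkn and Krtdap, at 252, 374 and 854 CPM against at most 85.3, 143 and 275 CPM elsewhere. Another on chromosome 7 (43712567 to 43796757) held Klk13, Klk11, Klk10 and Klk9. In RFP- MHCIIlo a run of 9 genes on chromosome 6 (52156902 to 52215076) held Hoxa2, Hoxa3 and Hoxa5, at 12.9, 12.2 and 5.21 CPM against at most 3.16, 2.39 and 1.44 CPM elsewhere. Runs in RFP- MHCIIlo with interferon-inducible genes among their members lay on chromosome 11 (48861968 to 49051242, with Irgm1 at 81.0 CPM against at most 37.2 CPM elsewhere) and chromosome 19 (34241090 to 34613401, with Ifit3 at 78.0 CPM against at most 23.0 CPM). The first run also held predicted or unnamed genes, and the second the smooth muscle actin gene Acta2, Ch25h and a predicted gene. In RFP+ MHCIIhi runs held Fabp9, Fabp4 and Fabp12 on chromosome 3 (10193621 to 10301183), H19, Igf2 and Ins2 on chromosome 7 (142575529 to 142743381), with Igf2 at 105 CPM against at most 40.8 CPM elsewhere, and Hoxc11, Hoxc12 and Hotair on chromosome 15 (102936757 to 102957708), with Hoxc11 at 25.8 CPM against at most 5.07 CPM. In RFP- MHCIIhi the runs on chromosome 13 (21715763 to 22043676 and 23744973 to 23860716) held 7 genes each, of which 6 and 5 were histone genes, the others being Prss16 in the first and Trim38 and Slc17a3 in the second.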
